A study of Nothobranchius furzeri with 18 samples.

How the data were processed

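RNA was measured by sequencing of polyadenylated transcripts in primary fibroblasts grown from tail tissue of the African turquoise killifish, Nothobranchius furzeri, a short-lived fish used in studies of ageing. The fish were wild type (WT) or homozygous for a mutation in exon 1 or in exon 3 of vgll3. Per the labels' protocols, cells were harvested near confluence, RNA was taken up in TRI Reagent, libraries were made with a KAPA mRNA HyperPrep kit, and single-end reads were produced on a NextSeq 2000. The file holds 18 libraries. Library names ending in A and B are technical replicates of 1 sample per the series design, which gives 10 samples, called cultures here: 3 exon 1 mutant, 3 exon 3 mutant and 4 WT. WT F1 and WT F9 carry no A or B. The labels do not say whether they are separate cultures or technical replicates of 1 culture; they were kept as separate cultures, which the number of 4 WT cultures rests on, and were summed as an alternative. The labels do not say that the cultures of a genotype came from separate fish, so p-values measure the spread between these samples, which may be technical.

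The authors deposited raw counts of reads per gene, with 1 value for each of 25099 genes in each library. All values are whole numbers of 0 or more. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.4, cutadapt 3.4, STAR 2.7.6a and edgeR 3.32.1, with no role or order. The genome build, the annotation, the rule for reads that match several genes and the use of strand are not given in the sources used here. Counts of near-identical paralogs and of overlapping genes are therefore uncertain. Totals per library ran from 15236208 to 28146560 counts. Mitochondrial transcripts took 1.54% to 4.77% of a library's counts, and the 10 most abundant genes took 6.7% to 8.7%. Intervals and floors based on counts cover counting error only, since reads without molecular identifiers are not independent molecules.

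Genes are named as in the file. Of the 25099 identifiers, 14280 are LOC numbers and 10819 are symbols. A total of 17480 matched the RefSeq gene table of assembly NfurGRZ-RIMD1, which gives a current name to 5241 of the LOC numbers, and those names are used with the LOC number beside them. Because the authors' build is not named, no coordinates are given, and RefSeq was used only for names, for which genes neighbour each other and for which chromosome a gene lies on.

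Counts of libraries A and B were summed per culture. Genes were filtered with filterByExpr by genotype, which left 16354 genes. Libraries were scaled by the trimmed mean of M values (TMM), and all 10 cultures were fitted in 1 model with a term for each genotype, so that the genotypes share an estimate of the spread. The test was edgeR's quasi-likelihood F test with robust dispersions (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.248. Fold changes are log2 values with a prior count of 0.125. Their SE was derived from the test, as the absolute fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD over cultures. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% Poisson interval. The comparisons were each mutant against WT, the mutants against each other, the mean of both mutants against WT, and the genes called in both mutants. Because both mutants were compared with the same WT cultures, the last was set beside 20 simulated data sets of unchanged groups, beside the overlap of independent lists and beside 6 divisions of the WT cultures.

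The 39 gene lists were fixed before the data were examined, as were the comparisons, the tests, most of the alternatives and the rule for named genes. Lists with at least 5 members tested were tested with camera in limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera was repeated with an estimated correlation, and fry was run as a test of whether a list's genes move 1 way or in either direction. The count of a list's members past the gene test is also given after adjustment over the list alone. Named genes were those past the test with a gene name, a mean of at least 5 CPM in 1 of the genotypes compared and ranges of the cultures that do not overlap, up to 10 per direction by fold change. Where fewer than 5 passed in a direction, the 5 with the smallest p are named and said not to have passed where they did not. For both mutants against WT, the 10 genes with the smallest p among those called in both are named. The known partners of Vgll3 in the Hippo pathway are named whatever their result where they were tested. The genes tead2, tead4 and wwtr1 were not analysed here under these names. Some genes that the rule takes are not reported here.

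The model was tested on simulated counts made from the means and totals of these cultures, for the exon 3 mutant against WT over 16171 genes. The changed genes all had a mean of at least 5 CPM, so recovery of genes at lower levels was not tested. The model recovered 13 of 67 genes changed 1.5-fold, 50 of 67 changed 2-fold and 60 of 66 changed 4-fold, with 6 calls among unchanged genes. Changes below 2-fold were therefore often missed at this number of cultures. The mitosis list, raised 1.3-fold in simulated counts, was called by camera at an adjusted p of 7.2e-18 over 16161 genes, with 0 of the other lists called. Each gene was drawn independently there, so this does not test how camera behaves when the members of a list are correlated.

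Alternatives were other scaling factors, no filter on low counts, DESeq2 1.42.0, limma-voom, all 18 libraries as separate samples or with culture as a random effect, library A or B alone, WT F1 and F9 summed, fits of 2 genotypes only, a test against a fold of 1.5, a block on the sample number, and leaving out each culture in turn. After the data were seen, alternatives were added that regroup or leave out WT libraries. The reported calls were also counted without those on 1 chromosome. All identifiers in the file were used, and no library was left out of the main results.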

Results

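Gene expression was measured in cultured tail fibroblasts of killifish with 3 genotypes, to compare cells with a mutation in vgll3 with wild-type cells. Vgll3 is a vestigial-like cofactor that binds TEAD transcription factors, which also bind the Hippo pathway effectors Yap and Taz. There were 3 exon 1 mutant, 3 exon 3 mutant and 4 WT cultures in 18 libraries. Library totals ran from 15236208 to 23582245 counts in the exon 1 mutant, from 18480697 to 25172664 in the exon 3 mutant and from 17915661 to 28146560 in WT. The libraries did not separate by genotype on the first principal component, which held 37.9% of the variance, 14.9% of it between genotypes. On it, the libraries of exon 3 culture 3 lay at 50.6 and 51.6 and exon 1 library 3A at 45.9. Its partner 3B lay at -26.4 and the other libraries between -26.7 and 7.86. The second component held 19% of the variance, 36.7% of it between genotypes.

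The labelled partner libraries of WT F4 and WT FM differed from each other in many genes. This was examined in genes on in some libraries of a genotype, at 1 CPM or more, and off in the rest, at 0.15 CPM or less. Labelled partners were alike in 12 of 12 such genes in the exon 3 mutant, in 1 of 4 in the exon 1 mutant and in 5 of 18 in WT. The heat map of these WT genes shows them per library. Exon 1 libraries 3A and 3B also differed, with deviations that correlated at -0.60 across genes, against -0.19 for F4A with F4B and -0.44 for FMA with FMB. They were summed as labelled, and only WT libraries were regrouped. Because the labelled WT partners did not pair, each count of genes against WT is also given with the WT libraries grouped in other ways, chosen after the data were seen. By on/off genes F1 was summed with F9, F4A with FMB and F4B with FMA. By level steps F1 was summed with F4A, F9 with FMB and F4B with FMA. Both leave fewer than 4 WT units, in pairs chosen because they look alike in these data. Calls lost there can therefore come from the grouping itself.

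**Figure D1:**
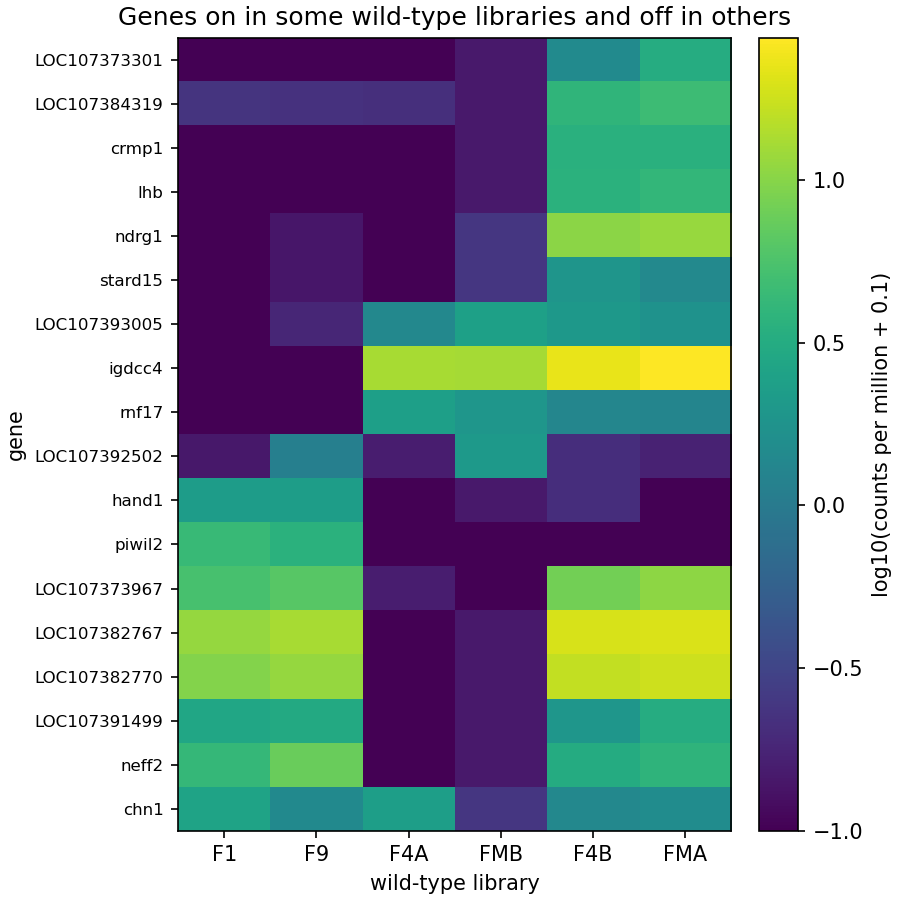
Heat map of the 18 genes that were on in some WT libraries and off in others, with 1 line per gene and 1 column per WT library. Colour is log10 of CPM plus 0.1, and the labelled partners F4A and F4B, and FMA and FMB, are alike in 5 of the 18 genes.

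The edited gene itself, vgll3, was reduced in the exon 3 mutant. A smaller decrease in the exon 1 mutant did not pass the test over all genes. Its level was 306 ± 30.4 CPM in WT (SD, n = 4), 245 ± 33.6 CPM in the exon 1 mutant (SD, n = 3) and 107 ± 10.3 CPM in the exon 3 mutant (SD, n = 3). The exon 3 mutant was lower than WT by a log2 fold change of -1.51 ± 0.14 (SE; edgeR, adjusted p = 0.00294). The exon 1 mutant did not pass the edgeR test against WT (log2 fold change -0.32 ± 0.14, SE, unadjusted p = 0.0423, adjusted p = 0.565). Nor did the mutants against each other (-1.19 ± 0.15, SE, adjusted p = 0.0518). The last value passed with upper-quartile scaling factors (adjusted p = 0.0298). For the mean of the mutants, vgll3 was lower than in WT by a log2 fold change of -0.91 (adjusted p = 0.011). That call was lost without WT F1 (adjusted p = 0.0518), F4 (0.0539) or FM (0.0604) and with the WT libraries regrouped (0.0506 and 0.0754). In single libraries, vgll3 ran from 98.5 to 119 CPM in the exon 3 mutant, from 198 to 326 CPM in the exon 1 mutant and from 229 to 382 CPM in WT. A mutation within an exon need not lower the count of the gene, so these levels are not by themselves a check of the genotypes. The submitters' library names hold KD for the exon 1 mutant and null for the exon 3 mutant.

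**Figure D2:**
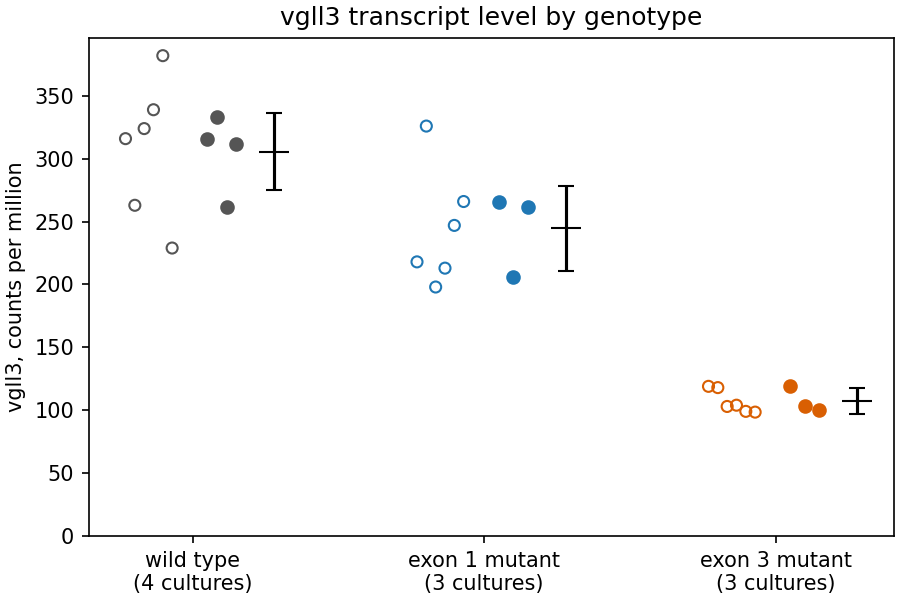
Level of vgll3 in CPM for each genotype, with open circles for single libraries, filled circles for cultures and a bar for the mean ± SD of the cultures. All exon 3 mutant libraries lie between 98.5 and 119 CPM, below the lowest WT library at 229 CPM.

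The partners of Vgll3 in the Hippo pathway differed by less than could be told from the spread between cultures. The level of yap1, the transcriptional coactivator restrained by Hippo signalling, was 99.3 ± 10 CPM in WT (SD, n = 4), 103 ± 13.3 CPM in the exon 1 mutant and 109 ± 5.67 CPM in the exon 3 mutant (SD, n = 3 each). None of yap1, tead1, tead1a (LOC107389211), tead3, tead3a (LOC107390951), vgll4 and vgll4a (LOC107391090) passed the test in any of the comparisons between genotypes. Their log2 fold changes were from -0.29 to 0.34. For each gene but tead1, the sign changed in at least 1 comparison under at least 1 alternative. Other values kept their sign over 25 alternative settings. Among these, tead1a ran from -0.32 to -0.18 in the exon 3 mutant against WT (edgeR, unadjusted p = 0.0437). In the exon 1 mutant vgll4 ran from -0.42 to -0.19. Against WT, tead3 ran from -0.43 to -0.06 in the exon 1 mutant and from -0.38 to -0.08 in the exon 3 mutant. Counts of the related genes vgll1, vgll2, vgll2b and vgll4l were 4, 10, 3 and 0 over all libraries, too few to test.

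In the exon 1 mutant, the matrix protein gene dpt (dermatopontin) rose from 2.65 ± 0.879 CPM in WT (SD, n = 4) to 20 ± 5.66 CPM (SD, n = 3), a log2 fold change of 2.90 ± 0.28 (SE; edgeR, adjusted p = 0.00337). The largest change among the named genes was in strbp, which encodes an RNA-binding protein of spermatids and was near the limit of detection in WT at 0.409 ± 0.14 CPM. It rose to 13 ± 0.787 CPM (log2 fold change 4.96 ± 0.31, SE; adjusted p = 0.000197). Smaller increases were seen in the scavenger receptor gene colec12 (log2 fold change 1.02), the lipid phosphatase gene ppap2d (LOC107378305; 0.98), the actin-depolymerizing factor gene dstn (0.96) and the carboxypeptidase gene cpz (LOC107393301; 0.77), with adjusted p from 0.0359 to 0.0477. The ubiquitin ligase gene rnf19a fell by 0.91 and cdkal1, which encodes a tRNA-modifying enzyme, fell by 0.85 on the log2 scale, with adjusted p of 0.0195 and 0.0448. Over 25 alternative settings, colec12 passed in 7, cdkal1 in 8, ppap2d and cpz in 10 each, dstn in 13 and rnf19a in 15. With the WT libraries paired by on/off genes none of these 6 passed, with adjusted p from 0.0644 to 0.154. Values for clec11a, which encodes a secreted bone growth factor (log2 fold change -1.92, adjusted p = 0.0611), pim3 (-0.79, adjusted p = 0.0651) and fhl3 (-1.26, adjusted p = 0.0881) did not pass.

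In all, 26 of 16354 genes were called in the exon 1 mutant against WT by edgeR, 18 higher and 8 lower, and 11 of them have no gene name. At an unadjusted p under 0.05 there were 1387. The share of higher genes among those called was 69.2%, but 39.9% by DESeq2, 42.7% with 18 libraries as separate samples and 37.1% in a fit of these 2 genotypes alone, so the balance of directions turned. The count was 5 without exon 1 culture 3, 5 without exon 1 culture 4, 9 without exon 1 culture 6, 16 without exon 3 culture 1, 56 without exon 3 culture 3, and 12, 10 and 9 without WT F1, F4 and FM. It was 6 and 12 with the WT libraries grouped in other ways. With WT F1 and F9 as the sole WT cultures it was 14, of which 8 were among the 26. Both strbp and dpt were called in each of these settings.

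Camera also called many gene lists when the same cultures were divided into other groups. Of 35 divisions, the real one included, 11 gave at least the 12 lists of the exon 1 mutant. For the exon 3 mutant, 35 of 35 gave at least its 5 lists. A list called by camera is therefore not by itself evidence of a difference between genotypes. Among the lists, the YAP/TAZ-TEAD target genes lay lower in the exon 1 mutant than other genes, with 21 of 26 members below 0 and a median log2 fold change of -0.37 (camera, adjusted p = 0.0012). This call was lost at adjusted p = 0.365 with an estimated correlation, and at 0.0718 with WT F1 and F9 alone. None of its members passed the gene test over all genes and 1 did adjusted over the list alone. Its members with the smallest p were thbs1b, which encodes a thrombospondin (log2 fold change -1.49 ± 0.36, SE; adjusted p = 0.21), amotl2b (-0.48) and cyr61 (-0.57). Immediate-early genes, which respond within minutes to growth signals, had a median of -0.50, with 26 of 31 members below 0 (adjusted p = 4.2e-07, and adjusted p = 0.365 with an estimated correlation). Their medians in the exon 1 cultures were -0.42, -0.78 and -0.14 relative to the WT mean, and dusp1 (-1.16) and ier2 (-1.33) were among the members with the smallest p. Cartilage genes had a median of -0.48 over 14 members (adjusted p = 0.0047, and adjusted p = 0.365 with an estimated correlation). In this list 2 members were past the test adjusted over the list alone, and without exon 1 culture 6 the adjusted p was 0.514. Lysosome and autophagy genes lay higher, with 46 of 63 members above 0, a median of 0.12 and 13 members higher at an unadjusted p under 0.05 (adjusted p = 0.000546, and adjusted p = 0.365 with an estimated correlation). Mitosis genes had a median of 0.33 with 65 of 66 members above 0 (adjusted p = 2.31e-07, and adjusted p = 0.778 with an estimated correlation). The exon 1 cultures differed, at 0.16, -0.09 and 0.81, and without exon 1 culture 6 the adjusted p was 0.521.

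The other lists called in the exon 1 mutant were cytosolic ribosomal proteins, higher with a median of 0.18, and, lower, Hippo pathway components (-0.12), matrix crosslinking and proteolysis (-0.16), inflammation and NF-kappaB targets (-0.14), the growth hormone and IGF axis (-0.02), the unfolded protein and integrated stress response (-0.05) and FGF and ERK signalling (-0.20). With an estimated correlation, 0 of the 12 called lists held, the smallest adjusted p being 0.365 and the largest 0.85, and fry for change in 1 direction called 0. Fry for change in either direction called 6 of the 39 lists, among them FGF and ERK signalling (adjusted p = 0.00244), cartilage (0.00761), YAP/TAZ-TEAD targets (0.0407) and lysosome and autophagy (0.0407). With WT F1 and F9 alone, the adjusted p was 0.329 for ribosomal proteins, 0.191 for Hippo components, 0.335 for matrix crosslinking and 0.367 for the growth hormone axis. It was 0.194 for both the unfolded protein response and FGF and ERK signalling. Without exon 1 culture 6, the adjusted p was 0.941 for cytosolic ribosomal proteins, 0.0848 for Hippo components, 0.284 for matrix crosslinking and proteolysis and 0.608 for the growth hormone and IGF axis. Leaving out exon 1 culture 4 gave 0.181, 0.205 and 0.232 for the last 3 of these and 0.225 for the unfolded protein response. The latter was also lost without exon 1 culture 3 (0.0618), WT F1 (0.231) and WT F4 (0.123). Without WT F4 the adjusted p was 0.0587 for Hippo components, 0.0872 for matrix crosslinking and 0.132 for the growth hormone axis. Without WT FM it was 0.144 for ribosomal proteins, 0.108 for matrix crosslinking and 0.0798 for the growth hormone axis.

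In the exon 3 mutant, dpt rose to 21.6 ± 5.07 CPM (SD, n = 3), a log2 fold change of 3.01 ± 0.28 over WT (SE; edgeR, adjusted p = 0.00294). Also higher were colec12 (log2 fold change 1.18, adjusted p = 0.0257), the kinase gene prkd2 (0.92, adjusted p = 0.0186), cpz (0.82, adjusted p = 0.0257) and txnip, which encodes an inhibitor of thioredoxin (0.77, adjusted p = 0.0374). Among the genes that fell were the cell adhesion gene cadm4, from 16.2 ± 1.55 CPM in WT (SD, n = 4) to 1.96 ± 0.48 CPM (SD, n = 3; log2 fold change -3.05 ± 0.47, SE; adjusted p = 0.0379), and ampd3b (LOC107372666), which encodes an AMP deaminase, from 11.9 ± 2.89 to 3 ± 0.596 CPM (-2.0 ± 0.24, SE; adjusted p = 0.0129). Also lower were the heparan sulfate sulfotransferase gene hs6st3 (-1.94), the adrenergic receptor gene adra1b (-1.57), vgll3 itself (-1.51) and the stress-inducible gadd45g (-1.23). The ciliary transport gene ift70 (LOC107374174; -1.11), the kinase gene pim3 (-0.96), the glutamine synthetase gene glula (LOC107383951; -0.96) and rnf19a (-0.87) were lower too. The adjusted p of these 8 genes was from 0.00294 to 0.0471. Over 25 alternative settings, ampd3b passed in 20, gadd45g in 18, hs6st3 in 17, prkd2 in 14, pim3 and rnf19a in 13 each, colec12 in 12, cpz in 11, adra1b in 9, and txnip, cadm4, ift70 and glula in 8 each. With the WT libraries paired by on/off genes, all of these but ampd3b were lost, with adjusted p from 0.0572 to 0.17.

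In all, 39 genes were called in the exon 3 mutant against WT by edgeR, 23 higher and 16 lower, 15 of them without a gene name, and 2017 had an unadjusted p under 0.05. The count was 7 without exon 3 culture 1, 18 without exon 3 culture 4, 25 and 15 without exon 1 cultures 3 and 4, and 7, 10, 24 and 7 without WT F1, F4, F9 and FM. The share of higher genes among those called was 59%, but 40% and 47.4% without exon 1 cultures 3 and 6 and 44.4% without exon 3 culture 4, so the balance of directions turned. Summing WT F1 and F9 as 1 culture left 12 genes called. The count was 6 and 5 with the WT libraries grouped in other ways. With WT F1 and F9 as the sole WT cultures it was 15, of which 6 were among the 39. Both dpt and vgll3 were called in each of these settings.

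Genes of bone-forming cells lay higher in the exon 3 mutant, with 21 of 23 members above 0 and a median log2 fold change of 0.93 (camera, adjusted p = 0.000148, and adjusted p = 0.882 with an estimated correlation). None passed the gene test over all genes and 11 did adjusted over the list alone. Exon 3 culture 3, whose libraries stood apart on the first principal component, carried most of this shift. The list's median relative to the WT mean was 1.62 in that culture, 0.02 in culture 1 and 0.51 in culture 4, and without culture 3 the adjusted p was 0.0381. The hypertrophic cartilage and bone collagen gene col10a1a was at 1950 CPM in culture 3, at 13.2 and 64.6 CPM in cultures 1 and 4, and at 6.32 to 21.2 CPM in WT. The gene sp7, which encodes a transcription factor of osteoblasts, was at 51.7, 0.525 and 4.98 CPM in cultures 3, 1 and 4. The mineralization inhibitor gene mgp behaved otherwise, at 242, 85.7 and 160 CPM in cultures 1, 3 and 4 against 43.5 to 65.3 CPM in the WT cultures. Its log2 fold change of 1.56 ± 0.30 (SE) did not pass (adjusted p = 0.0771).

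Genes of oxidative phosphorylation lay lower in the exon 3 mutant, with 58 of 61 members below 0 and a median of -0.29 (adjusted p = 4.17e-13, and adjusted p = 0.882 with an estimated correlation). Relative to the WT mean the list's median was -0.14, -0.62 and -0.17 in cultures 1, 3 and 4. Inflammation and NF-kappaB targets had a median of -0.37 (adjusted p = 1.34e-05, and adjusted p = 0.687 with an estimated correlation), and 7 members passed adjusted over the list alone. The members with the smallest p were the pentraxin gene ptx3 (log2 fold change -2.27, adjusted p = 0.0995) and the prostaglandin synthase gene ptgs2 (-1.05, adjusted p = 0.112). DNA replication genes had a median of -0.17 (adjusted p = 1.56e-05, and adjusted p = 0.882 with an estimated correlation). Relative to the WT mean this list was at -0.03, -0.44 and -0.07 in cultures 1, 3 and 4 and at -0.14 to 0.20 in the WT cultures, and without exon 3 culture 3 the adjusted p was 0.0381. Cytosolic ribosomal protein genes also had a median of -0.17, with 78 of 78 members below 0 (adjusted p = 1.34e-05, and adjusted p = 0.882 with an estimated correlation), but without exon 3 culture 3 the direction reversed, at an adjusted p of 0.227. Of these 5 lists, 0 were called with an estimated correlation, and fry for change in 1 direction called 0 of the 39. Fry for change in either direction called 12 of the 39, among them Hippo pathway components (adjusted p = 5e-06), a list that holds vgll3 itself, and inflammation and NF-kappaB targets (0.00299).

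Between the mutants, strbp and gpat2 passed the test. The level of strbp was 13 ± 0.787 CPM in the exon 1 mutant and 0.453 ± 0.199 CPM in the exon 3 mutant (SD, n = 3 each), a log2 fold change of -4.84 ± 0.35 from exon 1 to exon 3 (SE; edgeR, adjusted p = 0.000662). The level of gpat2 (LOC107394178), which encodes a glycerol phosphate acyltransferase, was 0.152 ± 0.0841 CPM in the exon 1 mutant, 5.73 ± 2.18 CPM in the exon 3 mutant and 3.31 ± 1.01 CPM in WT, a log2 fold change of 5.18 ± 0.50 between the mutants (SE; adjusted p = 0.00647). Genes with the next smallest p that did not pass were, higher in the exon 3 mutant, the peptide-processing gene cpe (log2 fold change 1.87, adjusted p = 0.106), odam (LOC107375246; 1.79, adjusted p = 0.125), ctnnd2a (LOC107383010; 1.77, adjusted p = 0.159) and arhgef12b (LOC107387127; 0.71, adjusted p = 0.164). Lower in the exon 3 mutant, and likewise not past the test, were vgll3 (-1.19, adjusted p = 0.0518), dstn (-1.05, adjusted p = 0.106), foxd1 (-1.88, adjusted p = 0.159) and ampd3b (-1.41, adjusted p = 0.164).

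Of 16354 genes, 2 were called between the mutants and 1387 had an unadjusted p under 0.05. The count was 1 without exon 1 culture 3 or 4, 8 without exon 1 culture 6, 4 without exon 3 culture 3 and 4 without WT F9. In each of 25 alternative settings strbp was called. A block on the sample number, which is not among the 25, called 0 genes with 1 residual degree of freedom. The call of gpat2 held in 17 of the 25. It was lost without exon 1 culture 3 or 4, with library A or B alone, by limma-voom on cultures or with culture as a random effect, in a fit of these 2 genotypes alone and with the WT libraries paired by on/off genes (adjusted p = 0.224), with adjusted p up to 0.253.

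Immediate-early genes lay higher in the exon 3 than in the exon 1 mutant, with 27 of 31 members above 0 and a median log2 fold change of 0.46 (camera, adjusted p = 4.78e-08, and adjusted p = 0.54 with an estimated correlation). The cultures overlapped, at 0.20, -0.22 and 0.24 relative to the WT mean in exon 3 cultures 1, 3 and 4 and at -0.42, -0.78 and -0.14 in exon 1 cultures 3, 4 and 6. Genes of matrix crosslinking and proteolysis had a median of 0.40 (adjusted p = 1.73e-05, and adjusted p = 0.54 with an estimated correlation), with 3 past the test adjusted over the list alone, and the collagen lysyl hydroxylase gene plod2 at a log2 fold change of 2.22 ± 0.54 (SE; adjusted p = 0.291). This list was at 0.01, 0.53 and 0.29 in the exon 3 cultures and at 0.01, -0.14 and -0.25 in the exon 1 cultures, and without exon 3 culture 3 the adjusted p was 0.0191. YAP/TAZ-TEAD target genes had a median of 0.23 (adjusted p = 0.00993, and adjusted p = 0.54 with an estimated correlation), and bone-forming cell genes of 0.56 (adjusted p = 0.00255, and adjusted p = 0.637 with an estimated correlation). Lower in the exon 3 mutant were DNA replication, with a median of -0.26 (adjusted p = 8.13e-10, and adjusted p = 0.54 with an estimated correlation), oxidative phosphorylation, of -0.28 (adjusted p = 8.29e-11, and adjusted p = 0.642 with an estimated correlation), and cytosolic ribosomal proteins, of -0.36 (adjusted p = 2.14e-13, and adjusted p = 0.645 with an estimated correlation). These shifts were largest in exon 3 culture 3. Relative to the WT mean, ribosomal proteins were at 0.19, -0.84 and -0.04 in exon 3 cultures 1, 3 and 4 and at 0.04, 0.04 and 0.48 in exon 1 cultures 3, 4 and 6. DNA replication was at -0.03, -0.44 and -0.07 in the exon 3 cultures and at -0.01, 0.05 and 0.16 in the exon 1 cultures. Oxidative phosphorylation was at -0.14, -0.62 and -0.17 in the exon 3 cultures and at -0.22, 0.01 and 0.18 in the exon 1 cultures. Without exon 3 culture 3 the adjusted p of these 3 lists was 0.0191, 1.91e-05 and 0.000235. Hippo pathway components (0.21), TGF-beta signalling (0.15), BMP signalling (0.26), the unfolded protein and integrated stress response (0.15), DNA repair (-0.15) and mitosis (-0.18) completed the 13 called lists, with adjusted p from 0.54 to 0.796 with an estimated correlation. The direction for mitosis reversed without exon 1 culture 6 (adjusted p = 0.177) and without exon 3 culture 3 (adjusted p = 0.0789). Without exon 3 culture 3 the adjusted p was also 0.329 for bone-forming cell genes and 0.145 for the unfolded protein response. The YAP/TAZ-TEAD targets were not called without exon 1 culture 4 (0.0828) or exon 3 culture 4 (0.0649). BMP signalling was lost without exon 1 cultures 3 (0.114) and 4 (0.214) or exon 3 cultures 3 (0.195) and 4 (0.107). With 1 regrouping of the WT libraries it was at 0.0506 and with WT F1 and F9 alone at 0.0627. TGF-beta signalling was lost without exon 1 cultures 4 (0.284) and 6 (0.161) or exon 3 cultures 1 (0.117) and 4 (0.235).

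Taking both mutants against WT, 16 genes were called in each mutant and changed the same way, 13 higher and 3 lower. LOC107395922 was at 0.237 ± 0.0459 CPM in WT (SD, n = 4), 3.62 ± 1.01 CPM in the exon 1 mutant and 3.44 ± 0.694 CPM in the exon 3 mutant (SD, n = 3 each), with a log2 fold change of 3.87 ± 0.28 for the mean of the mutants (SE; edgeR, adjusted p = 0.000739). LOC107372957 had 2 counts over the WT cultures, and its ratio to WT was 75.1 in the exon 1 mutant (95% Poisson interval 20.4 to 626) and 118 in the exon 3 mutant (32.2 to 976). LOC107383917 fell from 75.1 ± 13.5 CPM in WT to 5.87 ± 1.7 and 10.7 ± 6.69 CPM, and lypd6, which encodes a membrane-anchored modulator of Wnt signalling, from 3.03 ± 0.772 to 0.667 ± 0.0425 and 0.478 ± 0.0835 CPM. The membrane trafficking gene mal2, with 0 counts in WT, was at least 25-fold higher in the exon 1 mutant and at least 21.8-fold higher in the exon 3 mutant, against a floor of 3 counts over the WT cultures.

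**Figure D3:**
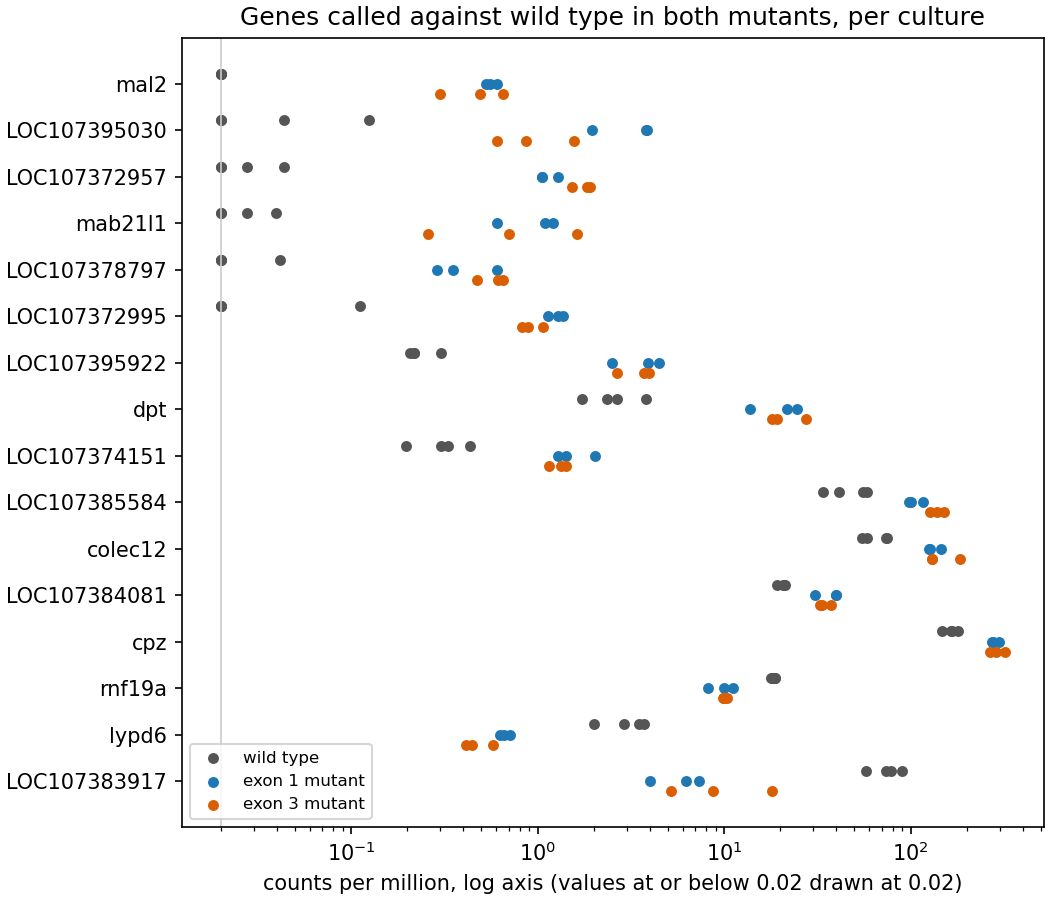
Level of the 16 genes called in both mutants against WT, in CPM on a log axis, with 1 point per culture and values at or below 0.02 drawn at 0.02. In each gene the 4 WT cultures lie apart from the 6 mutant cultures, as for dpt at a mean of 2.65 CPM in WT against 20 and 21.6 CPM in the mutants.

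Also called in both were dpt, cpz, colec12, LOC107385584, LOC107384081, LOC107372995, LOC107395030, LOC107378797, LOC107374151 and mab21l1, all higher, and rnf19a, lower. Of the 14 genes called in both with a place in RefSeq, 6 lie on the chromosome that carries gdf6a. They are LOC107395922, LOC107372957, LOC107378797, LOC107395030, mal2 and rnf19a. The expected number for independent lists was 0.0253 higher and 0.00783 lower. In 20 simulated data sets of unchanged groups that share a simulated WT group, the number was 0.05 on average and 1 at most. Unchanged groups give few calls to overlap, so the simulation does not show the overlap that shared WT cultures give among 26 and 39 calls. Across genes, which are not independent replicates, the fold changes of the mutants correlated at 0.49, against 0.44 in the simulated data, and their covariance was 0.128 against 0.052. The WT cultures were also divided so that each mutant had its own pair. Then 0 to 4 genes were called in both over 6 divisions, with correlations from 0.11 to 0.42. With the mutants averaged, 44 genes were called, 23 higher and 21 lower, and 1752 had an unadjusted p under 0.05.

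The number called in both was 4, 3 and 4 without exon 1 cultures 3, 4 and 6, 4 and 8 without exon 3 cultures 1 and 4, and 4, 4 and 3 without WT F1, F4 and FM. The number for the mean of the mutants was 28, 27 and 26 without exon 1 cultures 3, 4 and 6, and 16, 9 and 8 without WT F1, F4 and FM. Both other groupings of the WT libraries left 3 genes called in both, which were dpt, LOC107372957 and LOC107395922. With WT F1 and F9 as the sole WT cultures 9 were called in both, of which 4 were among the 16. Summing WT F1 and F9 as 1 culture left 7 called in both. The excess of higher genes was smaller or absent in other settings, with 56 higher and 46 lower by DESeq2, 71 and 57 with 18 libraries as separate samples, 33 and 27 with culture as a random effect, and 4 and 4 without exon 3 culture 4.

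Over both mutants, inflammation and NF-kappaB targets lay lower, with 28 of 35 members below 0 and a median of -0.29 (camera, adjusted p = 5.1e-06, and adjusted p = 0.54 with an estimated correlation), and 6 members passed adjusted over the list alone. Cartilage genes had a median of -0.38 (adjusted p = 0.0248, and adjusted p = 0.794 with an estimated correlation), with 4 members past the test adjusted over the list alone, among them ucma, chad and mia at log2 fold changes of -2.34, -2.40 and -1.79 that did not pass over all genes. Oxidative phosphorylation (-0.14), immediate-early genes (-0.18), mitosis (0.26), bone-forming cells (0.46) and lysosome and autophagy (0.13) were the other lists called. With an estimated correlation 0 of these 7 lists held, with adjusted p from 0.54 to 0.861. The adjusted p for cartilage was 0.155 without exon 1 culture 6, 0.0873, 0.0544 and 0.0794 without exon 3 cultures 1, 3 and 4, and 0.0985 without WT FM. That for immediate-early genes was 0.332 without exon 1 culture 4, 0.141 without exon 3 culture 3 and 0.252 without WT F1. Bone-forming cell genes were at 0.0706 without exon 3 culture 3 and 0.0526 without WT F9, and mitosis at 0.0759 without exon 1 culture 6. With WT F1 and F9 summed, immediate-early genes were at 0.0844. With the WT libraries regrouped they were at 0.139 and 0.0733, and cartilage at 0.0733 in 1 regrouping. With WT F1 and F9 alone, cartilage was at 0.123 and lysosome and autophagy at 0.172.

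A further 21 lists were called in no comparison by camera, with medians from -0.40 to 0.61. They were collagens and structural matrix, contractile and smooth muscle genes, telomere maintenance, the p53 response and cell cycle inhibitors, the interferon response, steroid and thyroid hormone genes, adipogenesis and lipid storage, cholesterol synthesis, glycolysis and hypoxia response, heat shock and oxidative stress response, Wnt, Notch and hedgehog signalling, HOX genes, mesenchymal and fin patterning factors, and markers of skeletal muscle, keratinocytes, pigment cells, leukocytes, endothelium, neurons and Schwann cells, and pericytes and tendon. The smallest camera adjusted p among them was 0.05, for cholesterol synthesis in the exon 3 mutant. Tested by fry for change in either direction, 6 of the 21 were called in at least 1 comparison, among them markers of other cell types. Fry tests a list by itself, not against other genes, so a few differing members can be enough. For the mean of the mutants, 1752 of all 16354 genes had an unadjusted p under 0.05 by edgeR. Fry was not run over other divisions of the cultures. For the mean of the mutants its adjusted p was 9.86e-06 for endothelium, 0.0018 for leukocytes, 0.00202 for pigment cells and 0.0129 for neurons and Schwann cells. In the exon 3 mutant against WT it was 0.00144, 0.00234, 5.59e-05 and 0.00299 for these 4 lists, and 3 of 18, 3 of 15, 4 of 14 and 7 of 19 members passed adjusted over the list alone. In the exon 1 mutant it was 9.15e-05 for endothelium and 0.0407 for leukocytes, and between the mutants 0.0301 for pigment cells. The other lists called in this way were mesenchymal and fin patterning factors (0.00299 in the exon 3 mutant, 0.00686 between the mutants and 0.0428 for the mean) and the p53 response (0.0274 in the exon 3 mutant and 0.0285 for the mean).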

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

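The tests of the WT library partners, of the chromosomes and of the genes around strbp and gpat2 were chosen after the results they examine had been seen.

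In 4 of the 42 genes examined, 1 WT culture lay far from the other 3. Chance gives about 1 in 20 such groups. The level of glula was 364 CPM in WT F1 and 439 to 445 CPM in the other WT cultures. The level of cpe was 41.6 CPM in WT F1 and 30.3 to 31.6 CPM in the others. The level of arhgef12b was 43.3 CPM in WT F1 and 51.3 to 52.5 CPM in the others. LOC107395922 was at 0.305 CPM in WT F4 and at 0.207 to 0.218 CPM in the others. These levels rest on 11 counts in F4 and on 5, 5 and 11 in F1, F9 and FM, too few to tell the gap from counting error. The effects of the mutants against WT differed, exon 3 minus exon 1, by a log2 value of -4.84 for strbp and 5.18 for gpat2 (edgeR test of the difference, adjusted p = 0.000662 and 0.00647).

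Each count was also taken over other divisions of the same cultures into groups of the same sizes. For genes called in the exon 1 mutant against WT, 1 of 35 divisions, the real one, gave as many as 26, and the highest other gave 10. For the exon 3 mutant it was 1 of 35, with 39 in the real one and 1 in the highest other. For the mean of the mutants it was 1 of 100, with 44 against 5, and for genes called in both it was 1 of 100, with 16 against 1. For these 4 counts no other division gave as many as the real one, with the WT libraries grouped as labelled. The labelled WT partners did not pair, so the WT cultures may not be units of the same kind as the mutant cultures. Every other division also mixes genotypes, which can widen its fitted spread and lower its count. Other groupings of the WT libraries were not divided in this way, so chance is not excluded for these counts. For gene lists, other divisions gave more calls than the real one in each comparison. The numbers of lists called are therefore not evidence of a difference between genotypes. In the exon 1 mutant 11 of 35 divisions gave as many as the real 12, and the highest other gave 16. In the exon 3 mutant 35 of 35 gave as many as the real 5, with 15 in the highest other. For the mean of the mutants 88 of 100 gave as many as the real 7, with 20 in the highest other. Between the mutants, 10 divisions are too few for a share under 0.05. There, 1 of 10 gave as many as the real 2 genes, with 0 in the highest other, and 3 of 10 as many as the real 13 lists, with 16 in the highest other.

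The first pattern is that the WT libraries did not pair by their labels, with labelled partners alike in 5 of 18 genes that were on in some WT libraries and off in others. A candidate explanation is that libraries of F4 and FM were crossed: of the 13 genes that differ among those 4 libraries, 11 fit F4A with FMB and F4B with FMA, and 0 fit the labels. Among 165 genes with a clear step in level, 0 set a labelled WT pair apart, but the crossed pairs had 5 and 36 and F9 with FMB had 91, so crossed labels cannot be told apart from other mix-ups. Differences between dishes of 1 culture with right labels stay open: labelled partners were the pair set apart in 33 of 34 step genes in the exon 1 mutant and 422 of 423 in exon 3, which goes against them, but exon 1 partners were alike in only 1 of 4 on/off genes, and the deviations of 3A and 3B correlated at -0.60, lower than those of F4A and F4B (-0.19) or FMA and FMB (-0.44). No biological explanation was tested, since the labels give no other grouping of the WT libraries.

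The second pattern is that genes called for the mean of the mutants against WT share a chromosome, the one that carries gdf6a, a gene related to gdf6Y, a candidate sex-determining gene of this species. It held 9 of the 36 called genes with a place in RefSeq, against 893 of 12472 tested genes, and 6 of the 14 such genes called in both mutants, with an adjusted p of 0.0146 for the 9 genes over 19 chromosomes (Fisher's exact test, one-sided). This is consistent with a variant that differs between WT and mutant donor fish, and vgll3 itself lies on another chromosome. Donors of different sex cannot be told apart from this: the 9 genes lay a median of 424 genes from gdf6a against 591 for all tested genes there, and 9 genes are few (one-sided permutation p = 0.192). An effect of the vgll3 genotype stays open and was not tested.

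The third pattern is the difference between the mutants in strbp and gpat2. A strain or donor variant near these genes might account for it. Of the 40 nearest tested genes, 4 had an unadjusted p under 0.05 between the mutants, or 10% against 8.47% of other genes (Fisher's exact test, one-sided, p = 0.443). The explanation cannot be told apart from others, since 40 genes are few and a variant acting on 1 gene would leave its neighbours as they are. An effect of the different vgll3 mutations stays open and was not tested.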

How the results depend on the processing

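Regrouping the WT libraries, using WT F1 and F9 alone and counting calls without the gdf6a chromosome were chosen after the data were seen. Counts are in the order exon 1 mutant, exon 3 mutant and mean of the mutants, each against WT, then the mutants against each other, then genes called in both. The reported counts are 26, 39, 44, 2 and 16. The cause of a change was not tested unless given. With other scaling factors or no filter on low counts, each count stayed within 1.5 times. DESeq2 called 253, 507, 442, 174 and 102 genes. All 18 libraries as separate samples, which counts technical replicates as independent, gave 342, 567, 497, 278 and 128. Culture as a random effect in limma-voom gave 109, 246, 210, 46 and 60, with an estimated correlation of 0.307 between libraries of a culture. Library A alone gave 3, 10 and 13 against WT, 2 between the mutants and 2 in both. Library B alone gave 33, 11 and 36 against WT, 3 between the mutants and 7 in both. Both settings have fewer reads, but they also differ in which library stands for a culture, so the cause cannot be told. With WT F1 and F9 summed, the exon 3 mutant had 12 and both had 7. Fits of 2 genotypes gave 17 in the exon 3 mutant, 1 between the mutants and 6 in both. The mean of the mutants was not run there, since it needs all 3 genotypes. The stricter test against a fold of 1.5 gave 9, 5 and 11 against WT and 3 in both. Limma-voom on cultures gave 1 between the mutants. Divided WT cultures gave 2.17 in both on average.

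Pairing the WT libraries by on/off genes gave 6, 6, 20, 1 and 3. Pairing them by level steps gave 12, 5 and 16 against WT and 3 in both. Both pairings leave fewer WT units than the reported fit, in pairs chosen for likeness in these data. With WT F1 and F9 alone, fewer WT cultures, there were 14, 15 and 16 against WT and 9 in both. Of these, 8, 6, 6 and 4 were among the reported genes. Of the reported calls, 18, 30, 35 and 2 were not placed on the gdf6a chromosome, with no new fit. Genes without a place in RefSeq count among these, and 36 of the 44 genes called for the mean of the mutants have a place. Leaving out each culture gave 5 to 56, 7 to 38, 8 to 50, 1 to 8 and 3 to 17 genes. Sample numbers 3 and 4 occur in both mutants. With the number as a replicate block, edgeR called 0 genes between the mutants, with 1296 at an unadjusted p under 0.05 and 1 residual degree of freedom. Same-numbered cultures correlated across genes at 0.38 for number 3 and -0.21 for number 4. With 2 shared numbers this cannot tell whether the numbers pair the samples.

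For gene lists the reported counts are 12, 5, 7 and 13. An estimated correlation gave 0, 0, 0 and 0, as did fry for change in 1 direction. Fry in either direction gave 6, 12, 13 and 3. WT F1 and F9 alone gave 13 in the exon 3 mutant. Leaving out each culture gave 8 to 16, 5 to 9, 6 to 10 and 10 to 16 lists.

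The lower level of vgll3 in the exon 3 mutant passed under each alternative. For the mean of the mutants its log2 fold change did not pass with library B alone (-0.76), against a fold of 1.5 (-0.91), with WT libraries paired by on/off genes (-0.92) or by level steps (-0.94) or with F1 and F9 alone (-0.84), and was -0.98 to -0.86 on leaving out each culture. Between the mutants it passed with upper-quartile factors, no filter or DESeq2 (-1.19 each), with 18 libraries (-1.20), with culture as a random effect (-1.18) and without WT F9 (-1.19). It was -1.30 to -1.12 on leaving out each culture.

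Signs changed for 23 gene values and 3 list values, none past the test. With library A alone these included rps28 (-0.08) and rpsa (-0.08) in the exon 1 mutant, vgll4 (-0.08) in the exon 3 mutant, and yap1 (-0.13) and rpl35a (0.07) between the mutants. With library B alone they were yap1 (-0.14), tead3a (-0.05) and vgll4a (0.01) in the exon 1 mutant, and tead3 (0.25) and tead3a (0.04) between the mutants. WT F1 and F9 alone reversed tead1a in the exon 1 mutant (0.07) and vgll4 in the exon 3 mutant (-0.03). Leaving out each culture gave -0.05 to 0.12 for yap1 and -0.08 to 0.07 for tead1a (with 0.04 without WT F4) in the exon 1 mutant. It gave -0.07 to 0.11 for vgll4 and -0.02 to 0.13 for tead3a in the exon 3 mutant, and -0.14 to 0.08 for tead3 between the mutants. The adjusted p of the list of ribosomal proteins in the exon 3 mutant was 2.74e-14 to 0.227, reversed without exon 3 culture 3. That of mitosis between the mutants was 5.45e-10 to 0.177, reversed without exon 1 culture 6, and at 0.0789 without exon 3 culture 3. Other values kept their direction: 4766 gene values stayed on their side of the test, 310 no longer passed and 172 came to pass. For lists 489 values stayed and 137 no longer passed. In counts simulated at the depth of these cultures for the exon 3 mutant, 19.4% of 1.5-fold and 90.9% of 4-fold changes were recovered. The changed genes there had a mean of at least 5 CPM.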

Other observations

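The test of the genes around vgll3 was chosen after the results there had been seen.

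For the mean of the mutants, the members of the lysosome and autophagy list with the smallest p were gnsb (LOC107395870; log2 fold change 0.38 ± 0.09, SE), the mitophagy receptor gene bnip3 (0.43 ± 0.11), the cathepsin gene ctsf (LOC107381272; 0.46 ± 0.12) and the sulfatase gene sgsh (0.39 ± 0.11). None passed over all genes (edgeR, adjusted p from 0.137 to 0.21). In the exon 3 mutant, the matrix metalloproteinase genes mmp14b (LOC107384247) and mmp2 had log2 fold changes over WT of 0.61 ± 0.13 and 0.62 ± 0.16 (SE) and did not pass (edgeR, adjusted p = 0.107 and 0.163). The cartilage matrix gene comp had a log2 fold change of -1.55 ± 0.44 (SE) for the mean of the mutants and did not pass either (adjusted p = 0.208).

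Around vgll3, 6 of the 20 nearest tested genes had an unadjusted p under 0.05 between the mutants, 5 of them higher in the exon 3 mutant. That is 30% against 8.45% of other genes (Fisher's exact test, two-sided, p = 0.00503). After adjustment over all genes edgeR called 0 of the 20, and neighbouring genes are not independent of each other.

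Pairs of libraries of a genotype were compared only to look for a library present more than once, with a measure that covers counting error alone. The chi-square per degree of freedom was 6.22 to 249 between labelled partners and 10.7 to 278 between other libraries. No pair was therefore close enough to be counted as 1 library. The 249 was between exon 1 libraries 3A and 3B, against 50 for F4A with F4B and 57.5 for FMA with FMB.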
